A study of Picea abies with 40 samples.

How the data were processed

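Gene expression was measured by RNA sequencing of total RNA in 40 libraries from Norway spruce seedling roots grown on plates. Per the labels' protocols, RNA of the 4 zones was extracted with chloroform and isoamyl alcohol and cleaned on RNeasy columns, and RNA of the laser-captured regions was extracted with the RNAqueous-Micro kit. The libraries followed a standard Illumina preparation per the labels. Because extraction and input differed between both kinds of sample, no group of either of the 2 tables was tested against a group of the other. Gene sets chosen in either table were tested within the other. Per the submitters' processing notes, Trimmomatic, STAR and HTSeq were used. Their versions, the reference genome, the annotation and the strand setting are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and genes with a near-identical copy may share or lose reads.

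The values deposited by the authors are raw read counts per gene, whole numbers with a different total in each library, in 1 table of the 20 zone libraries and 1 of the 20 captured libraries. Both tables list 70736 gene IDs and hold no summary rows. No column was left without a sample. The stele columns of the captured table carry the letter Z, the number of the stele and a replicate letter but not the word stele, and were assigned by elimination, since the QC area and ground tissue columns are named apart. The zone columns of the zone table are headed in the same form, with Z and the zone number, and the sources do not say whether equal numbers mark the same place along the root. Library names of the QC area (marked Qcmer), ground tissue (marked endo) and stele 1 all start with 1 in the labels. Library totals were 3.53 to 7.25 M counts in the zone table and 4.94 to 12 M in the captured table. Replicates of each group differed by more than sampling noise. The smallest chi-square per gene between 2 replicates of a group was 1.90, so no libraries were merged.

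Each table was analysed on its own with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default settings, which left 27767 genes in the zone table and 27239 in the captured table, holding at least 98.8% and 99.6% of the counts of each library. Libraries were scaled with TMM, with factors of 0.926 to 1.07 and 0.753 to 1.23. glmQLFit was run on all groups of a table together, with the group as the single term, so that groups shared an estimate of the spread, and glmQLFTest was run on each contrast with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled totals. Peak genes passed this threshold with a log2 fold change of at least 1 against each other group of the table. The zone peak sets were tested in the captured libraries with limma 3.58.1 (voom, camera with a preset inter-gene correlation of 0.01 or an estimated one, and fry), with adjustment over 20 tests. The genes named are the 2 IDs with the largest rise and the 2 with the largest fall per comparison among genes past the threshold, with a mean of at least 10 CPM over both groups and no overlap between their replicates. For each peak set they are the 2 IDs with the largest minimum log2 fold change over the other groups and at least 10 CPM in the peak group. Where the lower group had no count, a fold is given as a bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, a ratio is given with an exact binomial 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

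Pathway lists and cell type markers had been chosen by product name. The files do not pair their IDs with names and no annotation was used here, so these lists could not be applied and no cell type beyond the labels is named.

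The groups of each table share replicate numbers. The number was checked as a pairing by correlating, across genes, the deviations of same-numbered libraries from their group means. For zones 2 and 3 the 5 correlations ran from 0.122 to 0.336, so the numbers were taken to pair these libraries, although the labels do not say what the number stands for. For no other pair of groups were all correlations above 0.1. The main analysis had no replicate block, and the block was an alternative.

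The procedure was tested on simulated counts with 200 changed genes. For zone 2 against zone 1, over 26733 genes, 62.6% of genes changed 2-fold and 95.7% of those changed 4-fold were recovered, and 5.59% of the calls were false. For stele 1 against the QC area, over 26469 genes, 6.0% and 53.0% were recovered and 3.28% of the calls were false. Most simulated 2-fold differences were missed. The real comparisons called 15462 and 2574 genes, far more than the 200 changed here, which eases the adjusted threshold. These shares therefore need not hold for the real data. No other captured comparison was simulated.

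The alternatives tried were DESeq2's size factors and total counts in place of TMM, no filter and a stricter filter of 5 CPM, DESeq2 1.42.0, the replicate block, the lane as a covariate, a fit of only the groups compared, a minimum fold change, and leaving out each library in turn. Fits within a lane, a fit without stele 1 replicate 1 and stele 2 replicate 4 (each with the fewest detected genes of its group), and the permutation of set scores were added after the data were seen. Figures were drawn with matplotlib 3.10.9.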

Results

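Roots of Norway spruce (Picea abies) seedlings, a conifer, were profiled by RNA sequencing about 2 days after germination. Whole segments were cut in order from the root tip and numbered zone 1 to zone 4, with 5 libraries per zone. 3 segments were 1 mm long and 1 was 2 mm long. Laser capture microdissection, in which a laser cuts chosen cells out of a tissue section, gave 5 further groups of 4 libraries: the QC area, ground tissue, stele 1, stele 2 and stele 3. The stele is the central cylinder that holds the vascular tissue, and ground tissue lies around it. The abbreviation QC is used as the labels give it. The design text places the steles in the elongation and differentiation zones, without saying which stele number belongs to which.

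The 20 zone libraries held 3.53 to 7.25 M counts and 34697 to 39400 genes with a count. The 20 captured libraries held 4.94 to 12 M counts and 26310 to 34888 genes with a count. Replicates spread more in the captured table, with a biological coefficient of variation of 48.2% against 16.02% in the zone table. Both are single values for a whole table. The smallest chi-square per gene between 2 replicates, which also grows with library totals, was 5.61 in the QC area and 6.58 in ground tissue. It was 11.3, 33.7 and 19.7 in steles 1 to 3. The ranking of captured comparisons by genes called changed with the groups in the fit. All zone libraries came from lane 3. The 4 QC area libraries came from lane 8 and the 4 stele 2 libraries from lane 7, while ground tissue had 1 library in lane 7 and 3 in lane 8. Stele 1 had 2 libraries in each of these lanes, and stele 3 had 3 in lane 7 and 1 in lane 8. The labels do not say whether replicates of a group came from separate seedlings or pools, or whether captured regions shared seedlings. The p-values therefore set each difference against a spread between libraries that is estimated over all groups of a table. That spread may be technical, and the p-values are too small where replicates of a group shared a seedling or pool. Where regions of different groups shared a seedling, the tests left out that pairing, which can make the p-values too large. The files do not pair the gene IDs with names, so genes are given by ID only.

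Zone libraries separated by their place along the root. PC1, with 70.0% of the variance, ordered the groups from zone 1 to zone 4, and PC2, with 15.4%, set zones 2 and 3 apart from zones 1 and 4. Among 27767 tested genes, 24543 (88.4%) differed among the zones in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05. The mean of these genes was highest in zone 1 for 9165 (37.3%), in zone 4 for 8395 (34.2%), in zone 3 for 4399 (17.9%) and in zone 2 for 2584 (10.5%). Zone 1 was also lowest for the most genes, 9806 (39.95%), ahead of zone 4 with 7305 (29.8%). Among the captured regions 15420 of 27239 tested genes (56.6%) differed. Of these, 5992 (38.9%) were highest in stele 3, 3624 (23.5%) in the QC area, 2784 (18.1%) in ground tissue, 1982 (12.9%) in stele 2 and 1038 (6.73%) in stele 1. Stele 3 was also lowest for the most genes, 6224 (40.4%), ahead of the QC area with 4442 (28.8%). PC1 of the captured table, with 58.2% of the variance, ran from the QC area and ground tissue through stele 1 and stele 2 to stele 3. Stele 1 libraries lay far apart on it, from -124.9 for replicate 3 to 4.67 for replicate 1.

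**Figure D1:**
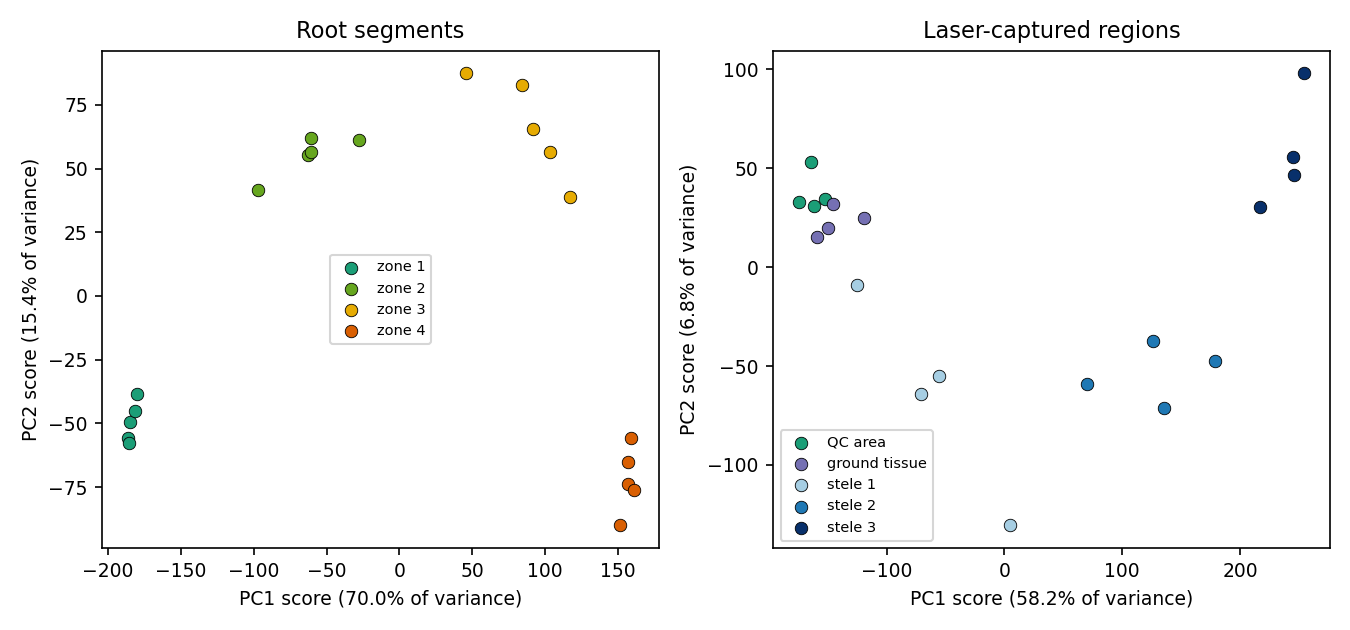
Principal component scores of the zone libraries (left, 5 per zone) and the captured libraries (right, 4 per region), 1 point per library; axes are PC1 and PC2 scores with their percent of variance. Zones follow each other along PC1, which holds 70.0% of the variance, and captured regions run from the QC area to stele 3 along a PC1 with 58.2%.

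The comparison of zone 2 with zone 1 asked what differs between the segment at the tip and the next. 7799 genes were higher in zone 2 and 7663 were lower, out of 27767 tested (50.4% higher, and 45.7% with DESeq2's size factors). MA_14092g0010 rose from 0.0751 ± 0.106 CPM (SD, n = 5) in zone 1, where it had 2 counts in all, to 71.5 ± 21.2 CPM (n = 5) in zone 2. That is a ratio of 952 with a 95% counting interval of 263 to 7864 (edgeR adjusted p = 2.26e-14). MA_651584g0010 rose from 0.213 ± 0.385 to 103 ± 86.9 CPM (n = 5 each), a log2 fold change of 8.93 ± 0.81 (SE, edgeR adjusted p = 2.84e-09). 4 of its 5 counts in zone 1 came from replicate 4, without which 1 count remained and the ratio was 2365, with a 95% counting interval of 424 to 93440. Without zone 2 replicate 3 its log2 fold change was 8.31. MA_101711g0010 was at 24.4 ± 3.24 CPM (n = 5) in zone 1 and had no count in zone 2, at least 202-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 2.59e-11). MA_96764g0010 fell from 80.9 ± 12.9 to 0.0761 ± 0.170 CPM (n = 5 each), where 2 counts remained, both in replicate 5, a ratio of 1008 with an interval of 279 to 8330 (edgeR adjusted p = 2.69e-12). Every library of the higher group lay above every library of the lower group for these genes. The rule for naming genes in the comparisons required this, but the rule for peak genes did not. Counting 2-fold changes alone left 3700 higher and 3282 lower genes.

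The comparison of zone 3 with zone 2 took the next step along the root. 7280 genes were higher in zone 3 and 7163 were lower (50.4% higher), and which side held more genes depended on the scaling, with 42.2% higher with total counts and 54.6% with DESeq2's size factors. MA_124502g0010 rose from 0.0687 ± 0.154 CPM, resting on 2 counts in replicate 3, to 40.6 ± 33.4 CPM (SD, n = 5 each), a ratio of 548 with a 95% counting interval of 151 to 4531 (edgeR adjusted p = 4.2e-08). MA_179122g0010 rose from 0.213 ± 0.312 to 57.5 ± 66.6 CPM (n = 5 each), a log2 fold change of 7.78 ± 1.01 (SE, edgeR adjusted p = 9.47e-07). 4 of its 6 counts in zone 2 came from replicate 3, without which 2 counts remained and the ratio was 602, with an interval of 166 to 4975. Without zone 3 replicate 3 its log2 fold change was 6.82. MA_10430569g0010 fell from 47.1 ± 18.8 to 0.374 ± 0.618 CPM (n = 5 each), a log2 fold change of -7.02 ± 0.47 (SE, edgeR adjusted p = 8.65e-11), and 6 of its 8 counts in zone 3 came from replicate 2, without which 2 counts remained and the ratio was 453, with an interval of 125 to 3746. MA_187851g0010 fell from 24.9 ± 9.86 to 0.344 ± 0.267 CPM (n = 5 each), a log2 fold change of -6.11 ± 0.45 (SE, edgeR adjusted p = 3.3e-10). Counting 2-fold changes alone left 3807 higher and 3166 lower genes. With total counts the median of all genes lay at -0.11 on the log2 scale, against -0.0090 with TMM.

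Zone 4 against zone 3 was the last step. 7246 genes were higher in zone 4 and 6334 were lower, so 53.4% of the called genes were higher, against 62.4% with total counts. MA_88684g0010 had no count in zone 3 and 58.5 ± 9.44 CPM (SD, n = 5) in zone 4, at least 463-fold higher against the floor of 3 counts over the group (edgeR adjusted p = 4.5e-10). MA_948664g0010 also had no count in zone 3 and 47.5 ± 12.4 CPM (n = 5) in zone 4, at least 376-fold higher (edgeR adjusted p = 4.51e-09). MA_44257g0010 fell from 36.2 ± 14.6 to 0.689 ± 0.71 CPM (n = 5 each), a log2 fold change of -5.80 ± 0.38 (SE, edgeR adjusted p = 3.62e-11), and 8 of its 16 counts in zone 4 came from replicate 1, without which the value was -6.51. MA_18599g0030 fell from 19.9 ± 12.1 to 0.439 ± 0.279 CPM (n = 5 each), a log2 fold change of -5.45 ± 0.47 (SE, edgeR adjusted p = 2.23e-09), with zone 3 replicate 2 at 40.8 CPM and the other zone 3 libraries at 9.31 to 17.7 CPM. Counting 2-fold changes alone left 3350 higher and 2224 lower genes. With total counts the median of all genes lay at 0.14 on the log2 scale, against 0.037 with TMM.

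Genes with a peak in a zone, at least 2-fold above each of the other 3 zones with an adjusted p under the threshold in each contrast, lay mostly at the ends of the sampled root. A gene that rises or falls steadily along the zones can only peak at an end. Among genes that differed, the means of 4858 rose and those of 4493 fell at each step. Zone 1 had 2713 peak genes and zone 4 had 2457, against 364 in zone 3 and 68 in zone 2. In zone 4, 390 of them exceeded each other zone by 8-fold, in zone 1 117 and in zone 3 3, while zone 2 had 0. MA_96764g0010 and MA_38303g0010 led the zone 1 set. MA_38303g0010 reached 44.2 ± 5.01 CPM (SD, n = 5) in zone 1 and rested on 2 counts in zone 4, the closest zone, a ratio of 570 with an interval of 158 to 4714. MA_114982g0010 led the zone 2 set, with 70.2 ± 7.88 CPM (n = 5) against 12.3 ± 5.31 CPM (n = 5) in zone 1, followed by MA_10433303g0010 with 50.6 ± 5.76 CPM against 9.60 ± 6.14 CPM in zone 3. MA_34530g0010 had 36.4 ± 15.9 CPM (n = 5) in zone 3 and 4.06 ± 1.27 CPM (n = 5) in zone 4, and MA_748060g0010 had 132.6 ± 37.7 CPM and 16.2 ± 10.2 CPM there. MA_88684g0010 and MA_948664g0010, named above, led the zone 4 set. They also had no count in zone 1, where zone 4 was at least 523-fold and 424-fold higher. The number of zone 4 peak genes was 3884 with no filter on low counts, where more genes were tested. With no minimum fold change the peak sets of zones 1 to 4 held 6341, 643, 1597 and 5117 genes.

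Stele 1 against the QC area compared captured vascular tissue with the QC area. 2293 genes were higher in stele 1 and 281 were lower, out of 27239 tested, so 89.1% of the called genes were higher. MA_10432716g0020 had no count in the QC area and 56.8 ± 41.4 CPM (SD, n = 4) in stele 1, at least 783-fold higher against the floor of 3 counts over the group (edgeR adjusted p = 7.42e-06). MA_5051g0010 likewise had no count in the QC area and 33.3 ± 30.2 CPM (n = 4) in stele 1, at least 459-fold higher (edgeR adjusted p = 0.000426). MA_38303g0010, a zone 1 peak gene, fell from 204.0 ± 29.9 CPM in the QC area to 5.04 ± 4.6 CPM in stele 1 (n = 4 each), a log2 fold change of -5.31 ± 0.73 (SE, edgeR adjusted p = 0.000426). MA_136990g0010 fell from 57.2 ± 23.7 to 2.11 ± 2.22 CPM (n = 4 each), a log2 fold change of -4.75 ± 0.94 (SE, edgeR adjusted p = 0.00232), with 39 of its 63 stele 1 counts in replicate 2 and a value of -5.75 without that library. Within lane 8, with 2 stele 1 and 4 QC area libraries, 573 genes were higher and 191 lower. Lane 7 held no QC area library. The number called was 1650 with lane as a covariate, 1647 without QC area replicate 3 and 1710 without stele 1 replicate 1, and with only these groups in the fit the share of higher genes was 68.0%.

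Ground tissue against the QC area compared the captured tissue outside the stele with the QC area. 880 genes were higher in ground tissue and 412 were lower. MA_591608g0010 rose from 0.395 ± 0.562 to 241.0 ± 110.1 CPM (SD, n = 4 each), a log2 fold change of 9.22 ± 1.12 (SE, edgeR adjusted p = 7.05e-05), and 12 of its 16 QC area counts came from replicate 4, without which the value was 10.74. MA_483593g0010 rose from 0.441 ± 0.883 to 229 ± 169 CPM (n = 4 each), a log2 fold change of 8.93 ± 0.99 (SE, edgeR adjusted p = 4.02e-05). All 19 of its QC area counts came from replicate 2, without which the change was at least 2335-fold, and without ground tissue replicate 1 the log2 fold change was 8.32. MA_10429775g0030 fell from 84.3 ± 44.3 to 1.90 ± 0.586 CPM (n = 4 each), a log2 fold change of -5.46 ± 0.66 (SE, edgeR adjusted p = 6.74e-05). MA_12174g0010 fell from 23.4 ± 5.72 to 0.549 ± 0.370 CPM (n = 4 each), a log2 fold change of -5.36 ± 0.94 (SE, edgeR adjusted p = 0.00179). Within lane 8, with 3 ground tissue and 4 QC area libraries, 1043 genes were higher and 764 lower. Lane 7 held no QC area library. The number called was 712 without ground tissue replicate 1, 805 without QC area replicate 2 and 854 without QC area replicate 1, against 2238 with only these groups in the fit and 2010 with DESeq2.

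Stele 1 was also set against ground tissue. 1302 genes were higher in stele 1 and 340 were lower. MA_115880g0010 rose from 0.157 ± 0.314 CPM in ground tissue to 581 ± 279 CPM in stele 1 (SD, n = 4 each), a log2 fold change of 11.62 ± 1.33 (SE, edgeR adjusted p = 2.36e-05). All 7 of its ground tissue counts came from replicate 4, without which the change was at least 5676-fold. MA_320782g0010 had no count in ground tissue and 22.6 ± 31.7 CPM (n = 4) in stele 1, at least 305-fold higher (edgeR adjusted p = 0.00279), with stele 1 replicate 1 at 69.8 CPM and the other stele 1 libraries at 3.90 to 11.6 CPM. Without stele 1 replicate 1 it was at least 92.6-fold higher. MA_175772g0010 fell from 23.4 ± 5.93 to 0.0914 ± 0.183 CPM (n = 4 each), where 3 counts remained, all in replicate 4, a ratio of 237 with a 95% counting interval of 80.7 to 1149 (edgeR adjusted p = 0.000261). MA_279755g0010 fell from 28.1 ± 22.3 to 0.316 ± 0.451 CPM (n = 4 each), a log2 fold change of -6.37 ± 1.35 (SE, edgeR adjusted p = 0.00563), and 7 of its 10 stele 1 counts came from replicate 2, without which 3 counts remained and the ratio was 216, with an interval of 73.8 to 1051. Within lane 7, with 2 stele 1 libraries and 1 of ground tissue, 333 genes were higher and 25 lower, a fit in which the lone library is assumed to vary like the other groups. MA_320782g0010, MA_175772g0010 and MA_279755g0010 missed the threshold there, with so few libraries. MA_320782g0010 was at least 126-fold higher and MA_175772g0010 at least 69.5-fold lower in stele 1, each with no count in the lower group, and MA_279755g0010 had a log2 fold change of -6.73 ± 2.34 (SE). Within lane 8, with 2 and 3 libraries, 285 were higher and 131 lower, and MA_279755g0010 missed the threshold with 3 counts left in stele 1, a ratio of 118 with an interval of 40.1 to 573. The number called over both lanes was 1022 without stele 1 replicate 1.

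Stele 2 against stele 1 compared captured steles with consecutive numbers. 3378 genes were higher in stele 2 and 2444 were lower, so 58.0% of the called genes were higher, and scaling by total counts turned this share to 46.3%. MA_135096g0010 had no count in stele 1 and 106.8 ± 68.1 CPM (SD, n = 4) in stele 2, at least 1082-fold higher (edgeR adjusted p = 6.75e-05). MA_10427673g0010 had no count in stele 1 and 31.3 ± 36.7 CPM (n = 4) in stele 2, at least 317-fold higher (edgeR adjusted p = 0.000608), with stele 2 replicate 1 at 86.2 CPM and the other stele 2 libraries at 8.81 to 16.4 CPM. Without stele 2 replicate 1 it was at least 134.7-fold higher. MA_94115g0010 was at 20.4 ± 28.0 CPM (n = 4) in stele 1 and had no count in stele 2, at least 263-fold lower (edgeR adjusted p = 0.00108), or at least 84.8-fold lower without stele 1 replicate 3. MA_52821g0010 fell from 23.04 ± 12.9 to 0.0625 ± 0.125 CPM (n = 4 each), where 3 counts remained, all in replicate 2, a ratio of 325 with a 95% counting interval of 111 to 1578 (edgeR adjusted p = 0.000457). Within lane 7, with 4 stele 2 and 2 stele 1 libraries, 600 genes were higher and 53 lower, and MA_94115g0010, at least 76.4-fold lower, no longer passed; lane 8 held no stele 2 library. The number called was 3727 without stele 1 replicate 3 and 2634 with only these groups in the fit, and the median of all genes lay at -0.051 on the log2 scale, or at -0.22 with scaling by total counts.

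In stele 3 against stele 2 most called genes were lower. 1049 genes were higher in stele 3 and 2494 were lower, so 29.6% of the called genes were higher, against 13.8% with scaling by total counts. MA_19212g0010 rose from 0.624 ± 0.733 to 34.2 ± 25.1 CPM (SD, n = 4 each), a log2 fold change of 5.66 ± 1.04 (SE, edgeR adjusted p = 0.0068), or 6.38 without stele 2 replicate 2, and was not called by DESeq2. MA_132211g0010 rose from 4.44 ± 5.41 to 159.8 ± 79.6 CPM (n = 4 each), a log2 fold change of 5.16 ± 1.01 (SE, edgeR adjusted p = 0.00892), or 6.17 without stele 2 replicate 1. MA_10426777g0010 was at 20.9 ± 14.6 CPM (n = 4) in stele 2, with replicate 3 at 42.8 CPM and the others at 13.0 to 14.5 CPM, and had no count in stele 3, at least 148-fold lower (edgeR adjusted p = 1.37e-05). Without stele 2 replicate 3 it was at least 97.0-fold lower. MA_320782g0010 fell from 22.6 ± 27.2 to 0.134 ± 0.269 CPM (n = 4 each), where 3 counts remained, all in replicate 4, a ratio of 142 with a 95% counting interval of 48.5 to 691 (edgeR adjusted p = 0.00736), with stele 2 replicate 4 at 63.0 CPM and the other stele 2 libraries at 5.59 to 14.0 CPM. Without stele 2 replicate 4 the ratio was 64.2, with an interval of 21.7 to 313. Within lane 7, with 3 stele 3 and 4 stele 2 libraries, 105 genes were higher and 143 lower, and MA_132211g0010 and MA_320782g0010 no longer passed; lane 8 held no stele 2 library. In lane 7 the log2 fold change of MA_132211g0010 was 4.89 ± 1.07 (SE), and MA_320782g0010 had a ratio of 110 with an interval of 37.4 to 534. With only these groups in the fit 526 genes were higher and 485 lower, and the median of all genes lay at -0.11 on the log2 scale, or at -0.34 with scaling by total counts.

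**Figure D2:**
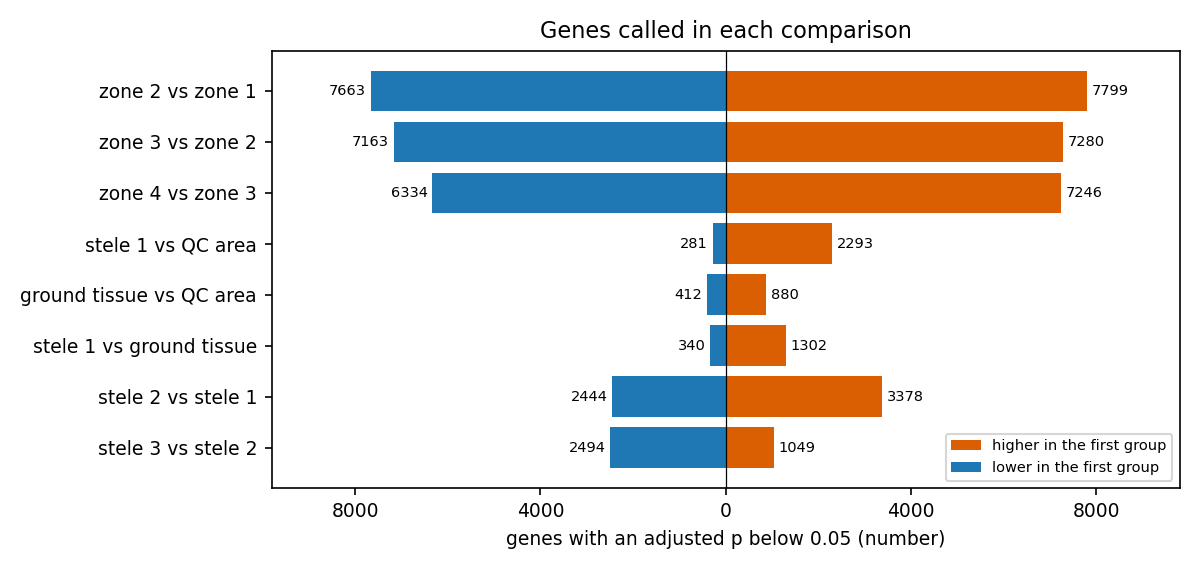
Number of genes with an adjusted p below 0.05 in each comparison (edgeR), with genes higher in the first-named group to the right of 0 and genes lower in it to the left. With TMM scaling the zone comparisons have 7246 to 7799 higher genes and 6334 to 7663 lower, while stele 1 against the QC area has 2293 higher and 281 lower. Bar lengths do not rank the captured comparisons. With only the groups compared in the fit, ground tissue against the QC area went from 1292 to 2238 genes. Stele 3 against stele 2 went from 3543 to 1011.

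Captured regions had fewer peak genes than the end zones, but the tests were of unlike power. In the captured table the biological coefficient of variation was 48.2%, against 16.02% in the zone table. It had 4 libraries per group against 5, and a peak gene had more contrasts to pass. Stele 3 had 604, ground tissue 90, the QC area 66, stele 2 9 and stele 1 2. The stele 3 libraries also had on average the lowest totals, 6.71 ± 0.468 M counts (SD, n = 4) against 8.96 ± 0.344 M in the QC area (n = 4), and the fewest genes with a count, 28870 ± 1047 against 32106 ± 1707. The library with the fewest, at 26310, was stele 2 replicate 4. Mean TMM factors were also lowest in stele 3, at 0.798 ± 0.0512 against 1.16 ± 0.0766, and its 10 highest genes held 8.14 ± 0.951% of the counts, the most on average, against 5.54 ± 0.275%. MA_413329g0010 reached 10.96 ± 12.8 CPM (SD, n = 4) in stele 3 with no count in the QC area, at least 151-fold higher, but was not called by DESeq2 and was at least 62.3-fold higher without stele 3 replicate 1. MA_19212g0010, named above, was the other leading stele 3 gene. MA_175772g0010 in ground tissue had 23.4 ± 5.93 CPM (n = 4) against 0.122 ± 0.245 CPM (n = 4) in stele 2, where all 5 counts were in replicate 3. MA_21316g0010 had 174.9 ± 100.9 CPM against 4.02 ± 4.14 CPM in stele 2, where replicate 4 held 66 of 147 counts. MA_108060g0010 had 12.3 ± 2.91 CPM (n = 4) in the QC area and 0.243 ± 0.121 CPM (n = 4) in ground tissue. MA_3099g0010 had 17.1 ± 6.95 CPM in the QC area and 0.624 ± 0.920 CPM in stele 1, where replicate 3 held 19 of 23 counts, and missed the threshold with DESeq2 and without QC area replicate 2 or 4 or stele 1 replicate 2. The 2 stele 1 peak genes were MA_120345g0010, with 37.8 ± 14.9 CPM (n = 4) against 12.5 ± 6.80 CPM in stele 3, and MA_10435890g0020, with 27.6 ± 10.6 CPM against 10.3 ± 6.69 CPM in stele 2. MA_48090g0010 in stele 2 had 10.2 ± 9.43 CPM (n = 4) against 1.61 ± 1.53 CPM in stele 1, with 28 of 46 stele 1 counts in replicate 4, and MA_131024g0010 had 97.6 ± 75.2 CPM against 25.5 ± 13.4 CPM in ground tissue. All 4 of these stele 1 and stele 2 genes missed the threshold without some single libraries: MA_120345g0010 without stele 1 replicate 1 or stele 3 replicate 2, and MA_10435890g0020 without stele 1 replicate 4 or stele 2 replicate 2, 3 or 4. MA_48090g0010 did so without stele 1 replicate 2 or 3 or stele 2 replicate 1, and MA_131024g0010 without ground tissue replicate 2 or 3 or stele 2 replicate 1. MA_10435890g0020 also missed it with lane as a covariate, and both stele 1 genes missed it without stele 1 replicate 1 and stele 2 replicate 4 together.

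The sizes of the captured peak sets moved with the libraries used. The stele 3 set held 356 genes without stele 2 replicate 3 and 966 with DESeq2, the ground tissue set 47 without ground tissue replicate 1, and the QC area set 30 without QC area replicate 2 and 103 with DESeq2. The stele 2 set ran from 2 genes without stele 3 replicate 1 to 20 without stele 2 replicate 4. The stele 1 set ran from 1 to 4 on leaving out 1 library, and was empty without stele 1 replicate 1 and stele 2 replicate 4.

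The zone peak genes, fixed from the zone libraries alone, were then followed in the captured regions, where stele 3 differed from the others on average in library totals, detected genes, TMM factor and the share of its 10 highest genes, as given above. For each captured library the set score was the mean over the set of log2 CPM centred on the gene's mean over the 20 captured libraries. Zone 1 peak genes, of which 2498 of 2713 were tested in the captured table, scored 1.27 ± 0.15 (SD, n = 4) in the QC area, 1.12 ± 0.20 in ground tissue and 0.64 ± 0.46 in stele 1, against -0.97 ± 0.60 in stele 2 and -2.06 ± 0.21 in stele 3. Zone 3 peak genes, 269 of 364, ran the other way, from -1.72 ± 0.07 (n = 4) in the QC area, -1.36 ± 0.22 in ground tissue and -0.86 ± 0.40 in stele 1 to 1.40 ± 0.41 in stele 2 and 2.54 ± 0.17 in stele 3. Zone 4 peak genes, of which 1333 of 2457 were tested, scored -0.62 ± 0.08 (n = 4), -0.72 ± 0.03 and -0.40 ± 0.12 in the QC area, ground tissue and stele 1, and 0.46 ± 0.30 and 1.28 ± 0.13 in stele 2 and stele 3. Zone 2 peak genes, 63 of 68, scored lowest in the QC area, at -1.67 ± 0.14 (n = 4), and highest in stele 2, at 1.24 ± 0.33, with -0.22 ± 0.27 in ground tissue, 0.52 ± 0.58 in stele 1 and 0.14 ± 0.25 in stele 3. In lane 7 the zone 1 score fell from 1.09 in the ground tissue library to 0.31 in stele 1, -0.97 in stele 2 and -2.01 in stele 3. In lane 8 it was 1.27 in the QC area, 1.13 in ground tissue, 0.96 in stele 1 and -2.20 in the stele 3 library. The zone 3 score in lane 7 was -1.51, -0.65, 1.40 and 2.51 in ground tissue and steles 1 to 3, and in lane 8 it was -1.72, -1.31, -1.08 and 2.64 in the QC area, ground tissue, stele 1 and stele 3. For zone 2 peak genes the lane 7 scores were -0.44, 0.66, 1.24 and 0.17 in ground tissue and steles 1 to 3. Their lane 8 scores were -1.67, -0.14, 0.38 and 0.024 in the QC area, ground tissue, stele 1 and stele 3. Stele 2 had libraries in lane 7 only and the QC area in lane 8 only, so neither could be compared with the other within a lane.

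Each set was tested in each region against the mean of the other 4 regions, 20 tests in all. limma's camera with a preset correlation of 0.01 called 18, and with an estimated correlation it called 17. Zone 2 peak genes in stele 1, with a median log2 difference of 0.89, were the call lost (adjusted p = 0.124 with an estimated correlation). limma's fry kept this call (fry adjusted p = 0.00149) and matched the preset correlation in all 20 tests as to what was called. fry was not run on regrouped libraries. Zone 2 peak genes were called neither in ground tissue, where the median was 0.56, the mean -0.17 and the direction of the camera test down, nor in stele 3. A two-sided exact permutation of the 20 libraries on the set scores, over 4845 splits and chosen after the data were seen, called 6 of the 20. With it zone 1 peak genes were lower in stele 3 (adjusted p = 0.00103, 4 of 4 libraries below 0), as were zone 2 peak genes in the QC area (exact adjusted p = 0.00103, 4 of 4 below 0) and zone 3 peak genes there (exact adjusted p = 0.0475, 4 of 4 below 0). Zone 2 peak genes were higher in stele 2 (exact adjusted p = 0.0223), and the sets of zones 3 and 4 were higher in stele 3 (exact adjusted p = 0.00103 each), with 4 of 4 libraries above 0 in each case. The permutation mixed libraries of all regions, so differences among the other regions made it harder to pass. Zone 1 peak genes in the QC area missed it (exact adjusted p = 0.066) with 4 of 4 libraries above 0. A set that missed this test is therefore not shown to be level. In 29 random regroupings of the captured libraries the preset correlation called a median of 15 and up to 18 of the 20, so the count of 18 does not stand out, while the estimated correlation called 0 in each of them.

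**Figure D3:**
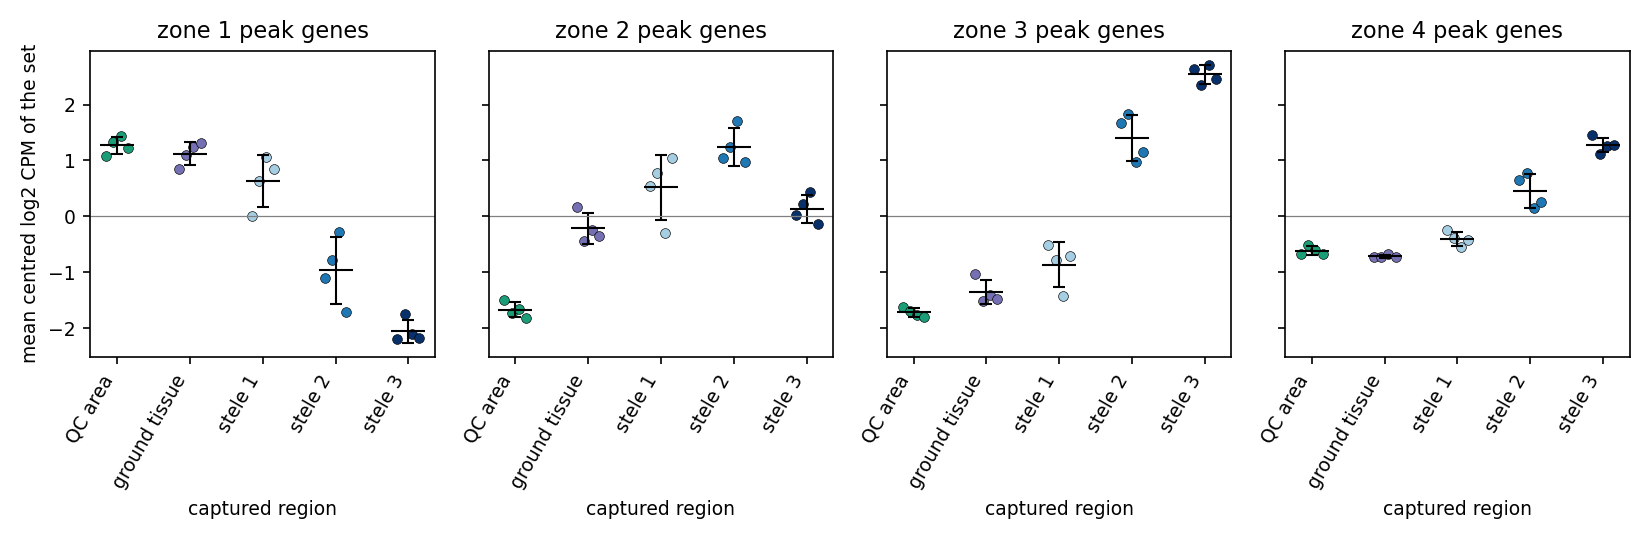
Scores of the 4 zone peak sets in the captured libraries (vertical axis, mean centred log2 CPM of the set), 1 point per library, with the mean of each region as a bar and the SD over 4 libraries as error bars. Zone 1 peak genes go from 1.27 in the QC area to -2.06 in stele 3, and zone 3 peak genes from -1.72 to 2.54.

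Fold changes between zone 4 and zone 1 and between stele 3 and stele 1 were correlated across genes, although the sources do not say where each stele number lies along the root. The column headers give steles and zones the same letter and numbers, without saying whether equal numbers mark the same place. The log2 fold change of zone 4 over zone 1 and that of stele 3 over stele 1, which share no library, had a Pearson correlation of 0.749 and a Spearman correlation of 0.723 over 23730 genes tested in both. This is a description across genes, which are not independent replicates, and it includes fitted values of genes with no count in a group. Of 9933 genes called in both comparisons, 9300 (93.6%) changed in the same direction. 4150 rose in both and 5150 fell in both, where independent lists of these sizes would share 1931 and 2507. The Pearson correlation was 0.692 with the stele libraries of lane 7 alone and 0.648 with those of lane 8, where stele 3 had 1 library.

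**Figure D4:**
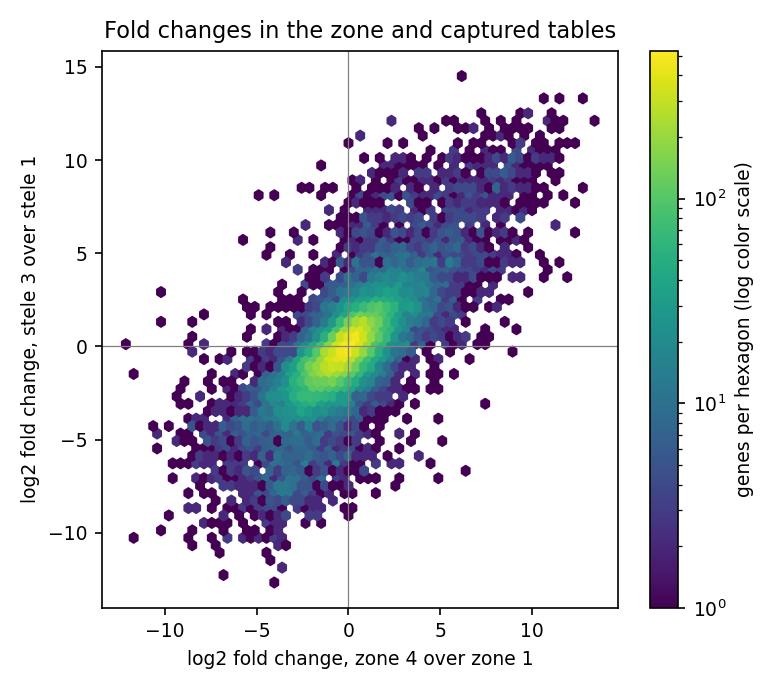
Log2 fold change of zone 4 over zone 1 (horizontal axis) against that of stele 3 over stele 1 (vertical axis) for 23730 genes, with the number of genes per hexagon on a log color scale. The cloud runs from lower left to upper right, with a Pearson correlation of 0.749.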

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

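No test in this part was chosen after its result was seen. Libraries that stood apart from the others of their group by the size of the gap to the nearest one were found in 7 of 81 groups of values examined, 36 of library measures and 45 of levels of named genes. For normally distributed values chance gives about 1 in 20 groups. Levels of genes named for large changes need not be so distributed, so 7 is no measure of an excess. Zone 4 replicate 3 held 7.25 M counts, and the other zone 4 libraries held 4.07 to 4.93 M. In stele 3 replicate 2 the 10 most counted genes took 6.71% of the counts, and in the other stele 3 libraries 8.56 to 8.70%. The other 5 were levels of named genes, each with 1 library above the rest. MA_320782g0010 stood apart in both steles in which it was named, with 69.8 CPM in stele 1 replicate 1 against 3.90 to 11.6 CPM in the other stele 1 libraries, and 63.0 CPM in stele 2 replicate 4 against 5.59 to 14.0 CPM in the other stele 2 libraries. MA_10427673g0010 was at 86.2 CPM in stele 2 replicate 1 and at 8.81 to 16.4 CPM in the others. MA_10426777g0010 was at 42.8 CPM in stele 2 replicate 3 and at 13.0 to 14.5 CPM in the others. MA_18599g0030 was at 40.8 CPM in zone 3 replicate 2 and at 9.31 to 17.7 CPM in the others. No explanation of these single values was tested.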

How the results depend on the processing

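The fits within a lane, the fit without stele 1 replicate 1 and stele 2 replicate 4 (each with the fewest detected genes of its group), the permutation of set scores and the regroupings with an estimated correlation were chosen after results were seen. The comparisons, their main tests, the other alternatives and the rule for named genes were set before the data were examined, and the tests of patterns in the other parts were not. No named gene, called set or correlation changed direction under an alternative run on it. The share of higher genes crossed an even split for stele 2 against stele 1 with total counts (46.3%), for stele 3 against stele 2 with only these groups in the fit (52.0%), and in the steps from zone 1 to zone 2 and from zone 2 to zone 3, but not from zone 3 to zone 4. Of the calls of named genes recomputed under the alternatives, 808 held and 28 were lost, all 28 in the captured table: 15 on leaving out 1 library, 6 in lane 7, 1 in lane 8, 3 with DESeq2, 1 with lane as a covariate and 2 without these 2 libraries. On leaving out 1 library, 7 of 20 fold changes of named genes in the zone table and 19 of 29 in the captured table moved by over 1.5 times. MA_96764g0010 between zones 1 and 2 enters these tallies both as a comparison and as a peak gene, which is the same contrast. With DESeq2's size factors, the stricter filter and the replicate block, all 19 counts stayed within 1.5 times and no named gene tested lost its call. The replicate block gave 14458 genes for zone 3 against zone 2, where the numbers were taken to pair the libraries, against 14443 without it, and changed no set call. The block was fitted over all zones with a common effect per number. It therefore cannot show how a pairing of zones 2 and 3 alone would change this count, and no block was fitted to these zones alone. For the other pairs of groups not every library correlated best with its own number, but a weaker pairing there is not excluded. For zones 1 and 3, 3 of 5 same-numbered pairs were each other's best match.

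The counts and other values that moved were these, and their cause was not tested unless fewer libraries, fewer genes or the threshold itself set it. A 2-fold minimum gave 6982, 6973 and 5574 genes for the steps from zone 1 to zone 4. Without a minimum fold, the peak sets held 6341, 643, 1597 and 5117 genes in zones 1 to 4 and 37 in stele 2. Without a filter zone 4 had 3884 peak genes. Total counts gave 5, 14 and 363 peak genes in steles 1 to 3. Lane as a covariate gave 1650 genes for stele 1 against the QC area and 1 stele 1 peak gene. With only the groups compared in the fit, ground tissue against the QC area had 2238 genes, stele 2 against stele 1 had 2634 and stele 3 against stele 2 had 1011. DESeq2 gave 2010 for ground tissue against the QC area and 103, 17 and 966 peak genes in the QC area, stele 2 and stele 3. Lane 7 alone gave 358 genes for stele 1 against ground tissue, 653 for stele 2 against stele 1 and 248 for stele 3 against stele 2. Lane 8 alone gave 764 for stele 1 against the QC area and 416 for stele 1 against ground tissue. Without stele 1 replicate 1 and stele 2 replicate 4, steles 1 to 3 had 0, 24 and 931 peak genes in edgeR, with 7 for stele 1 at an unadjusted p, and DESeq2 on all libraries gave 3 for stele 1. An estimated correlation ended the call of zone 2 peak genes in stele 1, with a median of 0.89 in both. The correlation of zone 4 over zone 1 with stele 3 over stele 1 was 0.812 over genes of at least 10 CPM, 0.692 in lane 7 and 0.648 in lane 8.

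Leaving out 1 library gave 1647 (without QC area replicate 3) to 3104 genes for stele 1 against the QC area, with 1710 without stele 1 replicate 1. It gave 712 (without ground tissue replicate 1) to 1081 for ground tissue against the QC area, with 805 and 854 without QC area replicates 2 and 1. It gave 1022 (without stele 1 replicate 1) to 2131 for stele 1 against ground tissue, and 3727 (without stele 1 replicate 3) to 6619 for stele 2 against stele 1. QC area peak genes ran from 30 to 81, with 30, 35, 35 and 39 without QC area replicates 2, 1, 4 and 3 and 31, 38, 38 and 41 without ground tissue replicates 1, 3, 4 and 2. Ground tissue peak genes ran from 47 (without ground tissue replicate 1) to 110, with 54 and 57 without QC area replicates 2 and 3. Stele 1 peak genes ran from 1, without stele 1 replicate 1 or 4, any stele 2 library or stele 3 replicate 2, to 4, without QC area replicate 1 or stele 1 replicate 3. Stele 2 peak genes ran from 2, 5 and 5 without stele 3 replicates 1, 2 and 3 to 14, 17 and 20 without stele 1 replicate 1 and stele 2 replicates 3 and 4. Stele 3 peak genes ran from 356 (without stele 2 replicate 3), 384 and 391 (without stele 3 replicates 1 and 3) to 757. Zone counts stayed within 1.5 times. In counts simulated for stele 1 against the QC area with 200 changed genes, the test missed most 2-fold differences. With more genes changed, as in the real comparison, this share may differ.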

Other observations

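The patterns weighed here were noticed in the data. The tests chosen only after a result was seen are the fits within a lane, the share of higher genes with only the 2 groups in the fit or with lane as a covariate, the regroupings with an estimated correlation, the exact permutation of set scores, the presence of zone peak genes in captured regions, and the demand that every pair of libraries stay above 0.1.

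Peak genes of the captured regions scored differently along the root. QC area peak genes, of which 45 of 66 were tested in the zone table, scored 1.60 ± 0.07 (mean centred log2 CPM, SD, n = 5) in zone 1 and -0.73 ± 0.07, -0.71 ± 0.08 and -0.17 ± 0.10 in zones 2 to 4. Ground tissue peak genes, 87 of 90, scored highest in zone 2, at 0.50 ± 0.14 (n = 5), with 0.18 ± 0.20 in zone 1, -0.27 ± 0.09 in zone 3 and -0.42 ± 0.10 in zone 4. Stele 3 peak genes, 541 of 604, scored -1.66 ± 0.06 (n = 5) in zone 1 and -0.50 ± 0.25 in zone 2, against 1.01 ± 0.25 in zone 3 and 1.15 ± 0.10 in zone 4. In a two-sided exact permutation of the 20 zone libraries over 15504 splits, with adjustment over 12 tests, QC area peak genes were higher in zone 1 (exact adjusted p = 0.000387, 5 of 5 libraries above 0). Ground tissue peak genes were higher in zone 2 (exact adjusted p = 0.000516, 5 of 5 above 0) and lower in zone 4 (exact adjusted p = 0.0089, 5 of 5 below 0). Stele 3 peak genes were lower in zone 1 (exact adjusted p = 0.000387, 5 of 5 below 0) and higher in zone 4 (exact adjusted p = 0.0197, 5 of 5 above 0), and missed the threshold in zone 3 (exact adjusted p = 0.0571). limma's camera with an estimated correlation called other sets in part. It called QC area peak genes higher in zone 1 (adjusted p = 0.000277) and lower in zones 2 and 3 (adjusted p = 0.000396 and 0.00491), and stele 3 peak genes higher in zone 3 (adjusted p = 0.0288). With it ground tissue peak genes in zones 2 and 4 (adjusted p = 0.0571 and 0.42) and stele 3 peak genes in zones 1 and 4 (adjusted p = 0.0571 and 0.0756) were not called, so QC area peak genes in zone 1 were the call that passed both tests. The permutation mixed libraries of all zones, so differences among the other zones made it harder to pass. QC area peak genes in zone 2 missed it (exact adjusted p = 0.0838) with 0 of 5 libraries above 0. camera sets a set against the other genes, so a call made by only 1 of these tests is not thereby refuted.

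Many zone 4 peak genes were low in every captured region. Of 2457 zone 4 peak genes, 1511 (61.5%, exact 95% interval 59.5 to 63.4%) reached a mean of 1 CPM in at least 1 captured region, against 2538 of 2713 zone 1 peak genes (93.6%, 92.6 to 94.4%). Fisher's exact test over genes, which are not independent, gave p = 5.08e-183. Among peak genes above 10 CPM in their zone the shares were 70.0% and 95.3% (Fisher's exact p = 1.52e-81). Zone 3 peak genes lay between, with 292 of 364 (80.2%).

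More genes were present in zone 4 and without a count in zone 1 than the reverse. Over all genes of the table, 1113 had a mean of at least 1 CPM in zone 4 and no count in the 5 zone 1 libraries, and 124 were the other way round. In libraries thinned to the smallest total the counts were 1268 and 175, a ratio of 7.25, and without 1 zone 4 library the ratio was at least 6.47, so neither library size nor a single zone 4 library accounts for the excess. Of the 1113 genes, 83 reached 1 CPM in zone 2 and 450 in zone 3, and 334 did so in stele 3 against 1 in the QC area and 0 in ground tissue. A difference between the segments stays open as a hypothesis, as does sequence from other organisms, which was not tested for.

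Genes called between stele 1 and the QC area leaned to higher in stele 1, at 89.1%. The lower share under DESeq2's size factors and total counts was 83.4%, and the lowest without 1 stele 1 library was 88.1%, which argues against the scaling and a single stele 1 library as the cause. With lane as a covariate it was 90.5%, with 1493 genes higher and 157 lower, which argues against the lane as the whole cause. In lane 8 alone, with all 4 QC area libraries and 2 of the 4 stele 1 libraries, the share was 75%, at the bound set for excluding the lane, and with only these 2 groups in the fit it was 68.0%. A part played by the lane, or by a spread estimated together with the other captured groups, cannot be told apart from a difference between the tissues. What keeps them open is that the share in lane 8 rests on 2 stele 1 libraries and lies at the bound, and that the share with 2 groups lies between both bounds.

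Same-numbered libraries of zone 2 and zone 3 deviated together from their group means, with a median correlation across genes of 0.198 against -0.049 for different numbers. Deviations from a group mean cancel over the group, so the value for different numbers follows largely from the first and is no separate evidence. In libraries thinned to the smallest total the median was 0.170, with every pair above 0.1, which argues against library size. After the part along the zone gradient was removed the median was 0.138 and the lowest pair 0.077. The correlation fell from 0.336 to 0.162 in replicate 2, from 0.231 to 0.077 in replicate 3 and from 0.122 to 0.099 in replicate 5. It went from 0.127 to 0.138 in replicate 1 and stayed at 0.198 in replicate 4, so the removed part did not carry the correlation there. A shared shift of the cut along the root may account for part of the fall in replicates 2 and 3. For the rest, such a shift and a shared pool or day cannot be told apart. On PC1 replicate 2 lay nearest to the tip-side end of both groups, at -97.2 in zone 2 and 45.6 in zone 3, and replicate 3 farthest from it, at -27.7 and 116.8. No biological explanation was tested.

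Consecutive IDs that share the part before the letter g had a median correlation of log2 CPM over the zone libraries of 0.680 over 1303 pairs, against medians of -0.090 to 0.112 in 1000 random pairings, and of 0.211 for deviations within the zones.

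Chance was weighed by regrouping the libraries and refitting with edgeR. For each pairwise comparison 1 split, the real one, gave as many genes. Over 40 splits of the 10 libraries, the steps from zone 1 to zone 4 had 14514, 11654 and 12525 genes with only the 2 groups in the fit, and the highest other split had 0, whatever number of replicate pairs it parted. Over all 35 splits of the 8 libraries, stele 1 against the QC area had 2067 genes, ground tissue against the QC area 2238, stele 2 against stele 1 2634 and stele 3 against stele 2 1011, with 0 in the highest other, and stele 1 against ground tissue had 1325 with 1 in the highest other. Over 30 groupings of a whole table, the real 24543 and 15420 genes that differed among zones and captured regions, and the peak sets of 2713, 68, 364 and 2457 genes in zones 1 to 4 and of 66, 90, 2, 9 and 604 genes in the QC area, ground tissue and steles 1 to 3, were each reached by 1 grouping, the real one, with 0 in the highest other. In each pairwise comparison taken alone, libraries exchangeable between the groups would rarely give the real split the most genes. These ranks over 35 splits, or a draw of 40, were not adjusted over the comparisons. They cannot exclude chance for all comparisons together. Libraries of zones 2 and 3, taken above to be paired, were split as if unpaired. A regrouping that mixes groups with real differences widens the spread within groups, so a highest other of 0 is no estimate of false calls, and for the counts over a whole table it speaks against all groups being alike, not for a single peak set such as the 2 genes of stele 1. Chance cannot be excluded for the 18 set calls of camera with a preset correlation, which 3 of 30 groupings reached, with 18 in the highest other. The 17 calls with an estimated correlation were reached by the real grouping alone, with 0 in the highest other, to which the same limit applies.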
